A study of Pleuronichthys verticalis with 38 samples.

How the data were processed

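Liver RNA of 38 hornyhead turbot was measured on a custom 8 x 15K Agilent array with 1 colour (Cy3), 1 array per fish and no pooling. Per the file headers, spot intensity was extracted by the authors with Feature Extraction 11.5.1.1. The deposited scanner files hold, for each of 15743 spots, the processed signal (background-subtracted intensity on a linear scale), the median spot and background intensity and quality flags set by the software. The deposited table of intensity values of the whole series holds the same processed signals, with a largest difference of 0.497%, so no scaling between arrays had been applied to it; its columns have medians from 4.95 to 24.3, and the reason for its rounding stays unknown. Per the labels' protocols, RNA was isolated with a Trizol kit and labelled with a low-input amplification kit.

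Groups were taken from sample titles: seawater control, oil control, low PBDE, high PBDE, low PCB and high PCB, with 7, 6, 7, 6, 5 and 7 fish. Each sample is a separate fish. The description of seawater control 7 calls it a vehicle control whereas its title and source name a seawater control. It was kept with the seawater controls, and leaving it out or moving it were among the alternatives.

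The log2 processed signal of each spot was taken relative to the array's 75th percentile over 15207 non-control spots, as log2(signal) minus that percentile, with no floor needed. Of 14757 non-control probes, 14707 had 1 spot and 50 had 10 spots, which were averaged. A probe was kept when well above background on at least 5 arrays, the size of the smallest group, which 10502 were. A further 10 were left out because a spot had an outlier flag on some array and no other spot replaced it, leaving 10492. No non-control spot was saturated (0), and 5572 probes were well above background on all arrays. Outlier flags affected 8 to 27 spots per array. Where a probe was not well above background in any fish of a group, only a bound is given: the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the probe's own level and the lowest level among probes well above background. No fold is given where this bound is under 1. The bound allows only for the unknown level of the dim group. It does not cover the spread between fish or another background correction, so "at least" below refers to the group means of the main scaling.

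All 38 arrays were fitted in 1 linear model of group and sex (female, male, immature) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along an intensity trend. Each comparison was tested per probe with Benjamini-Hochberg adjustment over the 10492 probes at a threshold of 0.05, two-sided, and intervals are at 95%. Design, filter, comparisons and most alternatives were fixed before the data were examined. The fixed gene lists and the fixed rule for named genes could not be applied, because the files pair probes with contig numbers and no gene names and no annotation was used here. In their place the text names, per comparison, the 1 or 2 probes with the smallest p in each direction, a rule set after the files had been seen to lack names. Probes named outside it are said to have been chosen after their values were seen.

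The array files place the 38 arrays on 8 slides scanned on 3 days. With group and sex in the model, 1039 probes differed between slides and 818 between scan days at an adjusted p under 0.05. Fish of each group were spread over the slides, with at most 2 fish of a group on a slide, and slide 8 held 1 array (high PCB 32). Slide was therefore used as a block among the alternatives, and the sign within slides was compared for the named probes. Of their 32 tests, 22 had the same sign on all slides that held both groups and 10 on all but 1. These probes were picked by their p in the same arrays, so this agreement is partly built in. Neither this tally nor the signs on slides given per probe below are separate support. The estimated correlation of arrays on 1 slide was 0.111.

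The test was run on simulated data made from the real means and spreads of the 10492 probes, with 200 probes changed, over 10 runs per comparison. For high PCB against oil, 40.9% of 2-fold, 84.5% of 4-fold and 97.0% of 8-fold changes were recovered, and for low PCB against oil 25.7%, 77.3% and 92.0%. For low PBDE against oil the shares were 40.0%, 83.3% and 96.8%, for high PBDE against oil 42.2%, 86.1% and 97.0%, and for oil against seawater 42.4%, 84.2% and 96.5%. For females against males they were 61.8%, 94.6% and 98.6%. These shares hold when 200 probes change at once, since the Benjamini-Hochberg limit becomes stricter when fewer do.

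Alternatives were quantile normalization, normexp background correction (offset 50, on the median spot and background intensity, since the files used here hold no mean signal), no filter on dim probes, probes well above background on all arrays, no sex term, male fish only, slide as a random or fixed block, only the groups compared, seawater control 7 left out or placed with the oil controls, the authors' series table, seawater controls or both control groups as reference, and each fish left out in turn. Scan day as a block and the 2 immature fish left out were added after seeing the data. Similarity of exposures was measured by the correlation and covariance of their log2 differences from oil, beside 50 simulations of unchanged groups, drawn probe by probe without slides, and 20 splits of the oil controls into sets of 3. Outlying arrays and fish were sought with Dixon's ratio within groups. Other splits of the samples were drawn 99 times per comparison. Figures were drawn with Python 3.11.15.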

Results

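Gene expression was measured in the liver of 38 hornyhead turbot (Pleuronichthys verticalis), a bottom-living flatfish used as a sentinel of marine contamination. Fish received a single injection into the body cavity of either a mixture of polybrominated diphenyl ethers (PBDEs, flame retardants) or a mixture of polychlorinated biphenyls (PCBs, industrial fluids), dissolved in peanut oil, and were sampled after 96 h. The low and high PBDE doses were 0.5 and 5 µg per g body weight (7 and 6 fish), and the low and high PCB doses were 1 and 10 µg per g (5 and 7 fish). Oil controls (6 fish) received peanut oil alone, and seawater controls (7 fish) were not injected. The fish comprised 10 females, 26 males and 2 immature animals. The low PCB group held 4 females and 1 male, whereas the high PBDE group held no female.

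Each liver was hybridised to 1 custom array with 14757 non-control probes, of which 10492 were tested. Between 6113 (high PCB 32) and 10355 (seawater control 35) probes per array were well above background, and the 75th percentile of signal ranged from 43.6 (high PCB 32) to 194 (low PCB 33) intensity units. The number of arrays limits the precision of every comparison. All livers had similar profiles: across probes, the correlation between any 2 arrays lay between 0.924 and 0.963, with a median of 0.948 within groups and 0.946 between groups. Fish of 1 group differed at a typical probe by a residual SD of 0.56 log2 units. The spots of 16 repeated probes differed within an array by a median SD of only 0.06 log2 units, against 0.34 between arrays of different fish, which also holds differences of labelling, hybridisation and slide. The files pair the probes with contig numbers and with no gene names, and probes are therefore given by their identifiers, with at most 2 higher and 2 lower per comparison. Levels are log2 signals relative to the array's 75th percentile, and a negative level is a signal below that percentile.

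The comparison of the high PCB dose with oil injection asked what 10 µg per g PCBs changed in the liver beyond the vehicle. HT_SCCWRP_1757 was the only probe of 10492 that passed the limma test at an adjusted p under 0.05, and it was lower in exposed fish. Its level was -3.60 ± 0.52 (SD, n = 7) after the high PCB dose and -2.27 ± 0.42 (SD, n = 6) in oil controls, a log2 difference of -1.39 (SE 0.25, adjusted p = 0.0335), and all 7 exposed fish lay below the oil mean. The probe was well above background in 3 of 7 exposed fish and 6 of 6 oil controls, and the difference had the same sign on all 5 slides that held both groups. HT_SCCWRP_2641 had a log2 difference of -1.99 (SE 0.39, limma adjusted p = 0.0540), was also below the oil mean in 7 of 7 fish (well above background in 2 of 7, and in 6 of 6 oil controls), and did not pass. The probes with the smallest p among higher values, HT_SCCWRP_51343 (log2 difference 1.65, SE 0.43, limma adjusted p = 0.439) and HT_SCCWRP_26753 (0.96, SE 0.27, adjusted p = 0.471), did not pass either. At an unadjusted p under 0.05 there were 777 probes, 515 of them lower, where 524.6 would be reached by chance. The call at HT_SCCWRP_1757 ended in 11 of 15 other settings of the fit (limma adjusted p from 0.0606 to 0.772, log2 difference from -1.61 to -0.13), among them slide in the model (-1.26, adjusted p = 0.208), normexp background correction (-0.13, adjusted p = 0.772) and the comparison with seawater controls, whose level was -2.99 ± 0.49 (SD, n = 7; log2 difference -0.57, adjusted p = 0.435). It also ended without any 1 of 4 oil controls (8, 15, 45 and 47) or of 2 exposed fish (25 and 32), with adjusted p up to 0.159.

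**Figure D1:**
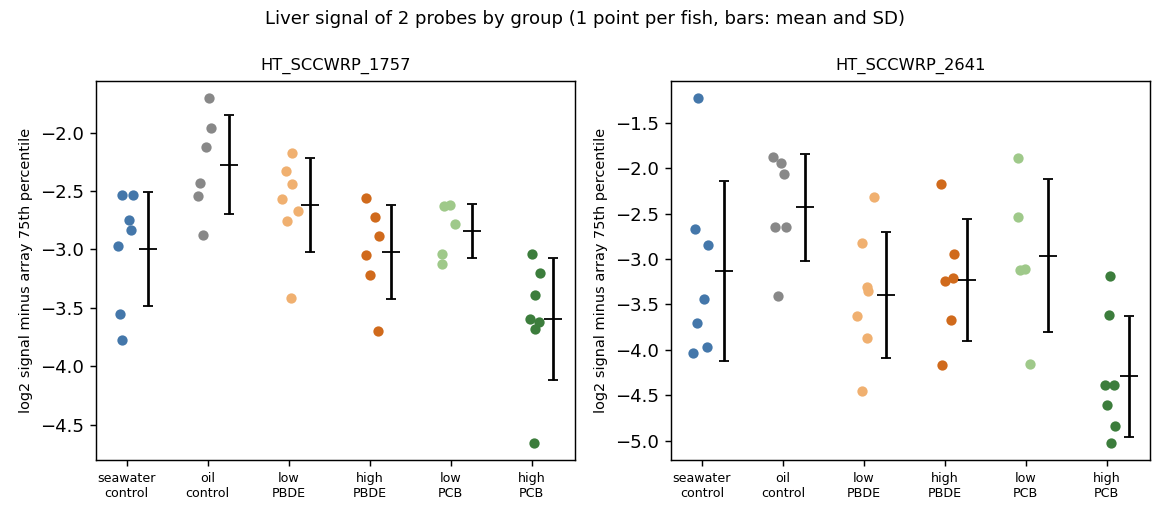
Log2 signal minus the array's 75th percentile (vertical axis) of HT_SCCWRP_1757 and HT_SCCWRP_2641 in the livers of the 6 groups, with 1 point per fish and bars for the mean and SD. For HT_SCCWRP_1757 the 7 high PCB fish lie between -4.65 and -3.04, and the 6 oil controls lie between -2.88 and -1.71.

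The low PCB dose was set against oil injection in the same way. No probe passed (0 of 10492, limma), and 788 were at an unadjusted p under 0.05. HT_SCCWRP_4949 had a level of 2.48 ± 0.56 (SD, n = 5) after low PCB and 1.00 ± 0.48 (SD, n = 6) in oil controls, with all 5 exposed fish above the oil mean (log2 difference 1.92, SE 0.44, limma adjusted p = 0.465). HT_SCCWRP_8292 was well above background in 3 of 5 exposed fish and in 0 of 6 oil controls, and no fold could be given for it. HT_SCCWRP_45273 (log2 difference -3.34, SE 0.80) and HT_SCCWRP_58946 (-2.38, SE 0.59) were below the oil mean in 5 of 5 exposed fish, and both had a limma adjusted p of 0.465. The interval of a typical probe in this comparison had a half-width of 0.77 log2 units, a factor of 1.71, and 4 of the 5 fish were female against 1 of 6 oil controls. Without low PCB 33, the male of the group, 1499 probes were at an unadjusted p under 0.05 and still 0 passed.

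Both PBDE doses were compared with oil injection. No probe passed at the low dose (0 of 10492, limma), with 462 at an unadjusted p under 0.05, and none at the high dose (0 of 10492), with 505. At the low dose HT_SCCWRP_4949 was again among the higher probes, at 2.54 ± 0.71 (SD, n = 7) against 1.00 ± 0.48 (SD, n = 6; log2 difference 1.52, SE 0.37, limma adjusted p = 0.998), and 7 of 7 fish lay above the oil mean. HT_SCCWRP_14760 was well above background in 4 of 7 low PBDE fish and in 0 of 6 oil controls, at least 1.31-fold higher (limma adjusted p = 0.998). HT_SCCWRP_14389 (log2 difference -1.35, SE 0.32) and HT_SCCWRP_31933 (-2.47, SE 0.62) were below the oil mean in 7 of 7 fish, with a limma adjusted p of 0.998 each. At the high dose HT_SCCWRP_26727 was well above background in 5 of 6 fish and in 0 of 6 oil controls, at least 1.46-fold higher (limma adjusted p = 0.588). HT_SCCWRP_1494 was well above background in 4 of 6 high PBDE fish and in 0 of 6 oil controls, at least 1.24-fold higher (limma adjusted p = 0.981). HT_SCCWRP_29625 (log2 difference -1.30, SE 0.30, limma adjusted p = 0.588) and HT_SCCWRP_6522 (-1.86, SE 0.52, adjusted p = 0.981) were below the oil mean in 6 of 6 fish. HT_SCCWRP_29625 had the same sign on all 5 slides that held both groups, and HT_SCCWRP_6522 on 4 of 5.

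The comparison of oil with seawater controls measured what the injection itself changed. No probe passed (0 of 10492, limma, smallest adjusted p = 0.207), but 759 were at an unadjusted p under 0.05, of which 472 were higher after oil injection. HT_SCCWRP_62788 was well above background in 6 of 6 oil controls and in 0 of 7 seawater controls, at least 1.87-fold higher (limma adjusted p = 0.207). HT_SCCWRP_11688 had a level of 3.61 ± 0.40 (SD, n = 6) after oil and 2.21 ± 0.64 (SD, n = 7) in seawater controls (log2 difference 1.44, SE 0.32, limma adjusted p = 0.207), and 6 of 6 oil fish lay above the seawater mean. HT_SCCWRP_34353 (log2 difference -1.01, SE 0.23) and HT_SCCWRP_1657 (-1.11, SE 0.27) were below the seawater mean in 6 of 6 oil fish, with a limma adjusted p of 0.207 each. HT_SCCWRP_11688 and HT_SCCWRP_62788 had the same sign on 5 of 5 shared slides, and HT_SCCWRP_34353 and HT_SCCWRP_1657 on 4 of 5. Without seawater control 24, 1 probe passed.

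Exposed fish were also compared with uninjected seawater controls, a reference chosen before the data were examined, against which exposure and injection combine. Against this reference 5 probes passed after low PBDE, all higher, 0 after high PBDE, 9 after low PCB (7 higher and 2 lower) and 8 after high PCB (6 higher and 2 lower), with limma, and 713, 858, 873 and 950 probes were at an unadjusted p under 0.05. The probes named here were chosen after their values were seen. HT_SCCWRP_14044 and HT_SCCWRP_15090 passed in 3 of the 4 exposures. These tests share the same 7 seawater controls, so the recurrence is partly built in. After high PBDE, where neither passed, their levels were 2.34 ± 0.24 and 0.36 ± 0.37 (SD, n = 6). After high PCB, where both passed, the levels were similar, at 2.37 ± 0.61 and 0.37 ± 0.71 (SD, n = 7). HT_SCCWRP_14044 had a level of 0.56 ± 0.84 (SD, n = 7) in seawater controls, 1.23 ± 1.24 (SD, n = 6) in oil controls and 2.60 ± 0.35 (SD, n = 7) after low PBDE, a log2 difference from seawater of 2.04 (SE 0.35, limma adjusted p = 0.00422). Its difference from seawater was 2.03 (SE 0.41, limma adjusted p = 0.0293) after low PCB and 1.77 (SE 0.35, adjusted p = 0.0307) after high PCB. HT_SCCWRP_15090 was -0.93 ± 0.46 (SD, n = 7) in seawater controls, -0.13 ± 0.45 (SD, n = 6) in oil controls and 0.82 ± 0.27 (SD, n = 7) after low PBDE, with differences from seawater of 1.75, 1.50 and 1.28 (SE 0.25, 0.29 and 0.25) after low PBDE, low PCB and high PCB. HT_SCCWRP_19679 was lower after both PCB doses, with levels of -0.19 ± 0.68 (SD, n = 5) and -0.13 ± 0.57 (SD, n = 7) against 1.42 ± 0.31 (SD, n = 7) in seawater controls (limma adjusted p = 0.0340 and 0.0285). Oil controls lay on the same side of seawater controls in all 22 passing tests, in 11 of them by more than 50% of the distance of exposed fish. This is partly built in, because both distances use the same seawater controls and the tests were selected for a large one. Some probes also count in more than 1 test, and no value for unchanged oil controls was computed. HT_SCCWRP_11688, which passed after high PCB (3.56 ± 0.25, SD, n = 7, limma adjusted p = 0.0342), was at 3.61 in oil controls and 2.21 in seawater controls. With slide in the model 3, 0, 13 and 6 probes passed after low PBDE, high PBDE, low PCB and high PCB. That an exposure passed or did not pass was not tested as a difference between exposures.

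**Figure D2:**
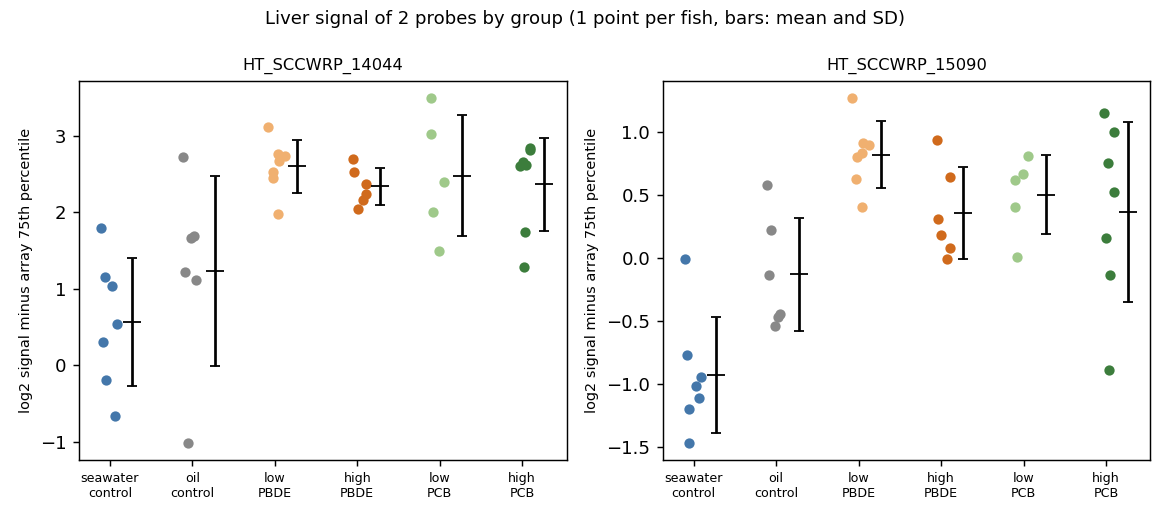
Log2 signal minus the array's 75th percentile (vertical axis) of HT_SCCWRP_14044 and HT_SCCWRP_15090 in the livers of the 6 groups, with 1 point per fish and bars for the mean and SD. Seawater controls have the lowest mean of both probes (0.56 and -0.93), oil controls the next (1.23 and -0.13), and each exposed group lies higher.

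The 2 doses of each mixture differed 10-fold. No probe passed between the high and low PBDE doses (0 of 10492, limma, 420 at an unadjusted p under 0.05) or between the PCB doses (0 of 10492, 319 at an unadjusted p under 0.05). The 95% interval of a typical probe had a half-width of 0.67 log2 units between PBDE doses and 0.74 between PCB doses. In the simulated data 36.9% and 31.2% of 2-fold changes were recovered, so such differences were not excluded. HT_SCCWRP_26727 was well above background in 5 of 6 high PBDE fish and in 0 of 7 low PBDE fish, at least 1.55-fold higher at the high dose (limma adjusted p = 0.131). It passed when sex was left out of the model (adjusted p = 0.0185) and without high PBDE 4 (adjusted p = 0.00998), and in limma fits over all settings its adjusted p reached 0.952. HT_SCCWRP_51185 was lower in 6 of 6 high-dose fish than the low-dose mean (log2 difference -2.20, SE 0.58, limma adjusted p = 0.999). Between the PCB doses HT_SCCWRP_1431 had a log2 difference of 1.65 (SE 0.43) and HT_SCCWRP_8721 of -1.75 (SE 0.41), high minus low, both with a limma adjusted p of 0.999. A test of whether the dose difference itself differed between the mixtures found 0 probes (limma, 316 at an unadjusted p under 0.05).

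PBDEs and PCBs are both halogenated 2-ring aromatic compounds, bridged by an oxygen atom in PBDEs, and carry bromine and chlorine, respectively. Their doses differed by mass (0.5 against 1 and 5 against 10 µg per g), so the mixtures were compared at the low and at the high dose and not at equal doses. No probe differed at the high doses (0 of 10492, limma, 415 at an unadjusted p under 0.05) or at the low doses (0 of 10492, 445 at an unadjusted p under 0.05). The 95% interval of a typical probe had a half-width of 0.66 log2 units (a factor of 1.57) at the high doses and 0.72 (a factor of 1.64) at the low doses. These intervals are not adjusted for the number of probes, whereas the test is. In the simulated data 41.2% of 2-fold and 83.3% of 4-fold changes were recovered at the high doses. At the low doses 37.6% and 82.4% were recovered, so 2-fold and some larger differences were not excluded. HT_SCCWRP_26727 was well above background in 5 of 6 high PBDE fish and in 0 of 7 high PCB fish, at least 1.20-fold higher (limma adjusted p = 0.706), and HT_SCCWRP_49519 had a log2 difference of -1.29 (SE 0.38, adjusted p = 1.00). At the low doses HT_SCCWRP_14052 was 0.94 log2 units higher after PBDEs (SE 0.24, limma adjusted p = 0.986). HT_SCCWRP_70640 was well above background in 0 of 7 low PBDE and 3 of 5 low PCB fish, at least 1.68-fold lower after PBDEs (limma adjusted p = 0.986). Without low PCB 33, 1 probe passed at the low doses.

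The 4 exposures shared their oil controls, which makes their differences from oil resemble each other by chance. Across the 10492 probes, which are not independent replicates, the correlation of log2 differences between exposures lay between 0.488 (high PBDE and low PCB) and 0.615 (low PBDE and high PCB), against a mean of 0.377 and 0.555 for the same pairs in 50 simulations with unchanged groups. For low and high PBDE it was 0.506, against 0.490. The simulations left out slides and links between probes, so their range does not give the spread by chance. When separate sets of 3 oil controls served as reference, the mean correlation over 20 splits ranged from 0.0113 (low and high PBDE, from -0.0794 to 0.135 in single splits) to 0.158 (low and high PCB, from 0.0920 to 0.222). The covariance differed from the mean simulated one by 0.0118 for the 2 PBDE doses and by 0.0518 for the 2 PCB doses. No probe passed in more than 1 exposure against oil, since only 1 passed at all.

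Females and males were compared with group in the model. No probe passed (0 of 10492, limma, smallest adjusted p = 0.0668), and 595 were at an unadjusted p under 0.05. HT_SCCWRP_9291 was lower in females, at -2.98 ± 0.72 (SD, n = 10) against -2.17 ± 0.56 (SD, n = 26), a log2 difference of -1.20 (SE 0.22, limma adjusted p = 0.0668) with 9 of 10 females below the male mean. HT_SCCWRP_6676 had a log2 difference of -0.73 (SE 0.15, limma adjusted p = 0.103). HT_SCCWRP_17842 (log2 difference 1.11, SE 0.25, limma adjusted p = 0.196) and HT_SCCWRP_4351 (1.96, SE 0.47, adjusted p = 0.380) were higher in females, and 10 of 10 females lay above the male mean for both. HT_SCCWRP_9291 passed without any 1 of 7 fish, among them low PBDE 12 (adjusted p = 0.00792). It did not pass with slide (log2 difference -0.93, limma adjusted p = 0.206) or scan day (-0.93, adjusted p = 0.190) in the model. Nor did it with normexp (-0.25, limma adjusted p = 0.999) or without high PCB 40 (-1.09, adjusted p = 0.329).

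**Figure D3:**
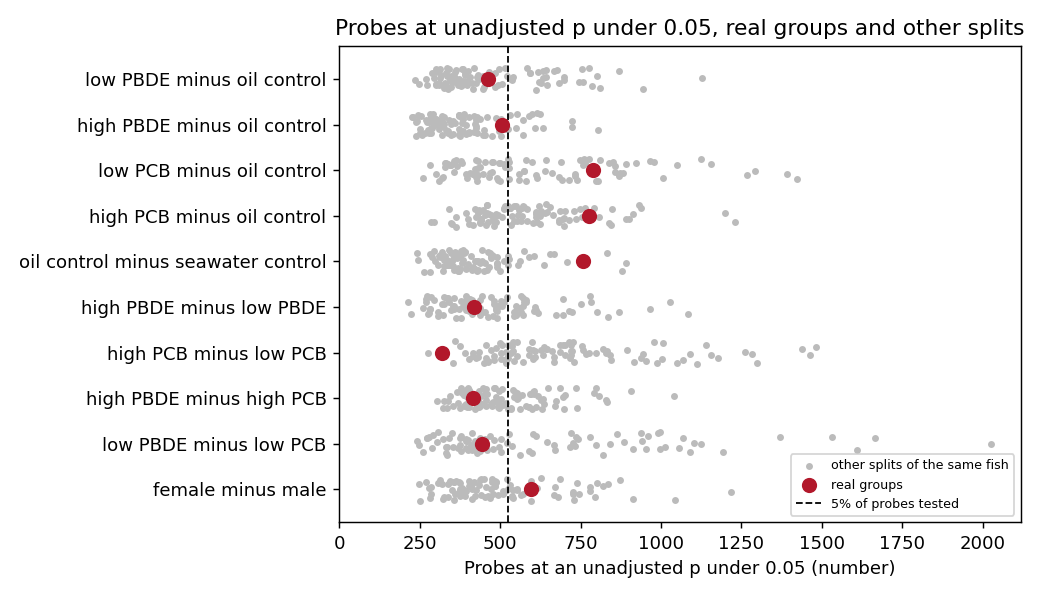
Number of probes at an unadjusted p under 0.05 (horizontal axis) in each comparison for the real groups (large points) and for 99 other splits of the same fish (small points), with a dashed line at 524.6, the number expected by chance. The oil against seawater comparison reached 759, with 890 the highest of its other splits, and in each other comparison at least 13 of 100 splits, the real one included, reached the real count.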

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

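A fish was taken as far from its group where its gap to the nearest of the others, relative to the group's range, exceeded Dixon's limit. This was asked of 3 measures per array in each group (18 tests) and of the probes named, in the groups compared (81 tests), and 7 values passed, where chance gives about 1 in 20. No explanation was tested for these values.

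High PCB 32, the dimmest array and the only array of its slide, had 6113 probes well above background, against 8282 to 9092 in the other high PCB fish. High PCB 41 had a mean correlation of 0.937 with the other arrays of its group, against 0.943 to 0.945 for these. Low PCB 39 stood apart on the other side, with a mean correlation of 0.949 against 0.940 to 0.941 in the rest of its group.

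Among the named probes, HT_SCCWRP_1757 was lowest in high PCB 41, at -4.65 against -3.68 to -3.04 in the other 6 fish. HT_SCCWRP_26727 was at -4.97 in high PBDE 4, the only fish of its group in which it was not well above background, and at -3.28 to -2.58 in the others. HT_SCCWRP_4949 was at 1.02 in low PBDE 48, against 2.46 to 3.14 in the other low PBDE fish. HT_SCCWRP_3011, named among the other observations, was at 4.95 in oil control 49, against 4.24 to 4.50 in the other oil controls.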

How the results depend on the processing

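Alternatives with scan day as a block and without immature fish were chosen after seeing the data. No paired analysis was possible because each fish has a number of its own and no number is shared between groups. The gene list alternatives were not run, since the files used here give no gene names. Of the counts of probes passing limma's test, the 1 probe of high PCB against oil changed most often. It became 0 with quantile normalization, normexp, no filter on dim probes, probes well above background on all arrays, no sex term, male fish only, slide or scan day as a fixed block, seawater control 7 placed with oil controls and both control groups as reference. In a fit of only the groups compared it stayed 1, but HT_SCCWRP_1757 no longer passed there (adjusted p = 0.465). It became 2 with slide as a random block, 3 without the 2 immature fish and 8 against seawater controls. The count of 0 for females against males became 1 with quantile normalization and with seawater control 7 placed with oil controls, and 2 without immature fish, which is also the fit of only these groups. Low PBDE against oil became 5 against seawater and 1 against both control groups, and low PCB became 9 against seawater and 1 in males, where it holds 1 fish, assumed to vary like the other groups. Male fish only also gave 1 for the low doses and 1 for the high doses of both mixtures compared, no sex term gave 1 for high against low PBDE, and fits of only the groups compared gave 1 for high PBDE against oil and 1 for high PBDE against high PCB. The cause of these changes was not tested, except that tests with fewer fish or probes differ by construction.

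With each fish left out in turn, the count for high PCB against oil ranged from 0 to 3: 0 without oil controls 8, 15, 45 or 47 or high PCB 25 or 32, 2 without high PCB 3, and 3 without oil control 20 or high PCB 41. For females against males it ranged from 0 to 4, with 4 without high PCB 41, 3 without low PBDE 12 and 1 without oil control 47, high PBDE 4 or 26, or low PCB 29 or 33. It ranged from 0 to 1 for oil against seawater (1 without seawater control 24), high against low PBDE (1 without high PBDE 4) and low PBDE against low PCB (1 without low PCB 33), and stayed at 0 for the other 5 comparisons. Without low PCB 33 the probes at an unadjusted p under 0.05 rose from 788 to 1499 for low PCB against oil, from 319 to 768 for high against low PCB, from 445 to 1028 for low PBDE against low PCB and from 595 to 1079 for females against males. Among other settings, 22 such counts moved by over 1.5 times, 8 of them with normexp and 9 with fewer probes tested. Of the counts of passing probes, 120 stayed equal or within 1.5 times and 26 did not. Most of the 120 were counts of 0 that stayed 0, which low power alone also gives. Among the named probes counted next, only HT_SCCWRP_1757 passed in the main fit, so most of their tests likewise stayed above the threshold. Of the named probes' tests, 430 kept direction and side of the threshold, 9 passed newly, 11 no longer passed and 3 turned sign, all 3 with normexp: HT_SCCWRP_14389 to 0.053 (low PBDE against oil), HT_SCCWRP_62788 to -0.12 (oil against seawater) and HT_SCCWRP_26727 to -0.0029 (high PBDE against high PCB). All 3 were dim, and normexp with an offset compresses dim probes by construction, which shrinks a difference but does not by itself turn its sign. Each of the 3 turned to the side on which the median of all probes lay with normexp, given next. Whether that shift turned them was not tested. With normexp the median log2 difference of all probes was -0.19 for oil against seawater (0.01 in the main fit). Against oil it was 0.13 for low PBDE and 0.12 for high PCB (-0.01 and -0.04 in the main fit). For high against low PBDE it was -0.14 (-0.045 in the main fit). For PBDEs against PCBs it was -0.13 at the high and 0.11 at the low doses (-0.005 and -0.02 in the main fit). Signal over background limits what can be seen at probes such as HT_SCCWRP_1757, well above background in 3 of 7 high PCB fish.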

Other observations

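The comparison of exposed fish with both controls was picked, after its result was seen, among 9 comparisons of pooled groups, and its other settings were chosen later. The tests for the choice among these 9, slide, array position and injection on it, for unadjusted counts against seawater controls, for HT_SCCWRP_26727, for dim spots and exposure group on the gaps, and for slide and exposure group on the co-varying set were also chosen after the values behind them had been seen. The average of the 4 exposed groups was set against the average of both control groups, which used all 38 fish. This comparison found 47 probes (limma, adjusted p under 0.05), 28 higher and 19 lower in exposed fish. All 47 had the same sign against oil and against seawater controls separately. This decides little, because the 47 were selected on the average of these 2 differences. The counts of fish and the median sizes given next carry the same selection. HT_SCCWRP_14044 was higher by 1.50 log2 units (SE 0.22, limma adjusted p = 0.00103), and 25 of 25 exposed fish lay above the control mean. HT_SCCWRP_15090 was higher by 1.06 (SE 0.16, adjusted p = 0.00103) in 24 of 25 fish. HT_SCCWRP_19679 was at 1.42, 0.95, 0.86, 0.35, -0.19 and -0.13 in seawater, oil, low PBDE, high PBDE, low PCB and high PCB fish, a difference of -0.96 (SE 0.19, adjusted p = 0.0152) shown by 22 of 25 exposed fish. HT_SCCWRP_3011 was at 4.61, 4.45, 4.07, 3.98, 3.74 and 3.50 in the same order, a difference of -0.73 (SE 0.14, adjusted p = 0.0152) shown by 23 of 25. The median size over the 47 probes was 0.58 log2 units against oil and 0.81 against seawater. Their median difference from oil was 0.53, 0.49, 0.80 and 0.57 after low PBDE, high PBDE, low PCB and high PCB. With oil controls alone as reference, 0 probes passed (limma, 793 at an unadjusted p under 0.05), and with seawater controls alone 54 passed, 29 of them among the 47. All injected fish, oil controls included, gave 35 against seawater controls (31 higher). Both PCB groups averaged gave 0 against oil (1002 at an unadjusted p under 0.05) and both PBDE groups 0 (512 at an unadjusted p under 0.05).

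Of 100 regroupings of all 38 fish, 1, the real one, gave 47 probes or more in this comparison, and the highest of the others gave 41 (an earlier draw with other random numbers had 1 as its highest). The regroupings moved fish freely across slides, and slide was not in their model. To allow for the choice among 9 pooled comparisons, the largest of the 9 counts was taken in each regrouping, and 2 of 100, the real one included, reached 47, with 114 the highest other. At the 5% level chance was thus excluded in these draws, although 1 regrouping other than the real one reached that count. With only 100 regroupings the share of 2 in 100 is a rough estimate, so this is not a firm exclusion. With slide in the model 33 of the 47 probes still passed with the same sign, which argues against slides as the whole cause. Injection of oil alone would leave exposed fish equal to oil controls, but over the 54 probes that differed from seawater the median difference of the averaged exposed groups from oil controls was 0.370 log2 units in the direction of the change, where 99 reshufflings of the injected fish gave 0.06 ± 0.12 (SD) and at most 0.349. Of their median difference of 0.88 from seawater, oil controls showed 0.53. Part of this 0.53 is built in, because the 54 probes were picked for their distance from the same seawater controls. Position on the slide cannot be told apart, because only 3 of the 47 passed with it in the model (median log2 difference 0.74 before and 0.70 after, median SE 0.16 and 0.18), and oil controls filled 4 of the 8 positions, although 0 probes differed between positions themselves (668 at an unadjusted p under 0.05).

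The count of 47 depended on single fish. It ranged from 12 without seawater control 6 to 90 without high PCB 41. It fell to 17, 25, 25, 24 and 22 without seawater controls 7, 22, 24, 35 and 50, to 21, 22, 14, 23 and 15 without oil controls 8, 20, 45, 47 and 49, and to 26, 26 and 24 without low PBDE 13, 38 and 51. It was 22 and 24 without high PBDE 18 and 23, 29 without low PCB 29 and 30 without high PCB 21, and it was 85, 75 and 71 without seawater control 46, low PBDE 12 and low PCB 33. Other settings gave 57 (quantile), 2 (normexp), 32 (no filter), 45 (probes well above background on all arrays), 44 (no sex term), 73 (slide as random block), 50 (slide fixed), 56 (scan day), 22 (no immature fish), 50 (seawater control 7 with oil), 47 (series table) and 0 in males, where the median difference was 0.67 with a median SE of 0.22.

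For other comparisons, splits of the same fish into groups of the same sizes were counted 100 times, the real one included. Taken alone, at a limit of 5 in 100 splits, chance can be excluded for the 759 probes at an unadjusted p under 0.05 between oil and seawater controls, which 4 splits reached (highest other 890), but 1 such result among 10 comparisons is not rare by chance. It cannot be excluded for low PBDE (462, 40 splits, highest other 1128), high PBDE (505, 17, 805), low PCB (788, 24, 1422) and high PCB against oil (777, 13, 1231). Nor can it for high against low PBDE (420, 56, 1084), high against low PCB (319, 99, 1481), high PBDE against high PCB (415, 75, 1039), low PBDE against low PCB (445, 55, 2027) and females against males (595, 25, 1217). These verdicts and those below do not allow for the number of comparisons. Their splits were drawn without regard to slide, and slide was not in the model. Some splits had several times the real count, such as 2027 against 445 and 1481 against 319. The source of such counts was not tested. Differences between fish, differences between slides and links between probes cannot be told apart here. For the single probe of high PCB against oil, 11 splits gave at least 1 and the highest other gave 1. Against seawater controls, chance can be excluded for the probes that passed after low PBDE (5 probes, 1 split, highest other 2), low PCB (9, 1, 4) and high PCB (8, 2, 21), and a count of 0 after high PBDE, which 100 splits reach by construction, decides nothing. Counts at an unadjusted p under 0.05 against seawater gave another picture. At the same limit chance can be excluded for high PBDE (858, 2 splits, highest other 998) and high PCB (950, 4, 1270). It cannot for low PBDE (713, 9, 968) and low PCB (873, 6, 1208). With only 100 splits such shares are rough estimates, so 4 and 6 do not separate high PCB from low PCB. The 4 splits of oil against seawater carry the same limit. With slide in the model the counts against seawater were 929, 1195, 870 and 1165 after high PBDE, high PCB, low PBDE and low PCB. No splits were drawn for them.

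HT_SCCWRP_26727 was well above background in 5 of 6 high PBDE fish and in 0 of the 32 other fish, which was noticed first and then tested. Its level did not separate the fish as fully, since the highest seawater control was at -3.21 and the lowest of the 5 high PBDE fish at -3.28. Among 511 probes seen in few enough fish, it was the only 1 well above background in 5 or more fish of a single group and in no other fish. Of 10000 regroupings of the fish, 294 (2.94%) gave at least 1 such probe, with 3 the highest, but this does not allow for the choice of the pattern after it was seen, and chance stays open. No other explanation was tested, and the gene behind the contig is not known here.

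A different kind of pattern was a wide gap between fish. At 17 probes, at least 3 fish lay more than 2 log2 units apart from the nearest of the rest, against 4 probes in values simulated with the same means and spreads. HT_SCCWRP_36740 was at 3.74 ± 0.69 (SD) in 6 fish and at -5.58 ± 0.66 in the other 32, with a gap of 6.62, and HT_SCCWRP_2305 was at 0.91 ± 0.82 in 33 fish and at -5.82 ± 0.46 in 5. No array lay on the smaller side of more than 6 of the 17 probes. Each side had to hold at least 3 fish, so a fault of a single array could not alone form a gap. The tally therefore decides nothing about faults of single arrays. Noise of dim spots is argued against at only 2 probes, HT_SCCWRP_9582 and HT_SCCWRP_43219, which were well above background in every fish. At the other 15 it cannot be told apart, because fish above the gap are bright by selection and some fish below it were not well above background. Whole groups could add up to a side at only 6 probes, and at all 6 some group had fish on both sides, so exposure group alone did not set the sides there. At the other 11 the group sizes force this outcome, and group cannot be told apart, since a smallest adjusted p of 0.990 (Fisher's exact test of side by group) does not exclude it. The sides of different probes had a median correlation of 0.117. Inherited differences at the probed sequences may be a source, a hypothesis that could not be tested without probe sequences or genotypes.

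The third pattern was a set of 18 probes, among them HT_SCCWRP_25169 and HT_SCCWRP_9059, that varied together and formed the largest cluster among the 60 most variable probes. Their mean ran from -2.59 (low PCB 33) to 5.97 log2 units (high PBDE 44), and their median pairwise correlation over the 38 fish was 0.953. Slides explained 14.5% of its variance (permutation p = 0.655) and the 6 groups 18.0% (permutation p = 0.248), so neither was its main source. RNA of another tissue in some liver pieces would move its transcripts in proportion, and on the linear scale the median pairwise correlation was 0.934, but the probes were picked by their correlation, so this decides nothing. Other tissue and a liver response shared by these genes cannot be told apart without gene names.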
